A study of Mus musculus with 7 samples.

How the data were processed

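CD4+ cells were sorted from mouse spleen by flow cytometry, per the labels' protocols. RNA was extracted with a column kit and DNase, and 150 ng of it went into each library, made with an Illumina TruSeq v2 kit, also per the labels' protocols. The deposited table holds RPKM values for 19589 gene symbols in 7 columns, 1 per library, and its column names match the labels of 4 WT and 3 RT samples. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool and the gene annotation are not given in the sources used here. Coordinates are those of GENCODE M21 for the same build, matched by gene symbol, and 19432 symbols were found there. The series describes the samples as separate mice. Nothing else says how they were bred, collected or sequenced.

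The planned test used the deposited RPKM values without further scaling. Genes at 1 RPKM or more in at least 3 of the 7 libraries were kept, and log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trended prior variance), with genotype as the only term. P-values are two-sided and were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes from this test are on the log2(RPKM + 1) scale, which understates the change of low genes. A set of 26 gene lists was tested with limma's camera at a preset correlation of 0.01, for lists with 5 or more genes kept, and again with an estimated correlation and with fry. The mean of log2(RPKM + 1) over a list was compared between groups with an exact permutation test over the 35 splits for 7 lists, the follicular helper list and 6 lists of other cell types. Unit, test and samples were those fixed before the data were examined.

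The depth of each library was worked out from the values. An RPKM value times the gene length and the library total is a whole number of reads if the authors counted whole reads. With GENCODE M21 exon lengths, 78.9% to 83.8% of the values under 100 reads in a library came out whole, within 0.01 reads. Letting each gene's length vary, 13053 of the 13859 genes above 0 gave whole reads in every library with a single length, and 806 needed a different length in the deep and shallow libraries (tolerance 0.003 reads). Gene models that differ between the deep and shallow libraries would give such lengths, but this was not tested. The reads recovered in genes were 49.4% to 52.9% of the total behind the values in the deep libraries and 88.7% to 92.2% in the shallow ones. A gene with 0 reads may have a level of up to 0.264 to 0.327 RPM (of 1000000 recovered reads) in the deep libraries and up to 26.7 to 30.9 RPM in the shallow ones, counting 3 reads as the limit. Such limits and intervals cover counting error only.

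The recovered reads were tested with limma voom, with terms for genotype and library set, over the 5896 genes with 10 or more reads summed over the shallow libraries. Library sizes were the sums of recovered reads. This fit, the library set term and the other fits on recovered reads were chosen after seeing the data. The deep libraries were also fitted alone (1 RT and 2 WT, where the lone RT library is assumed to vary like the wild-type ones), as were the shallow libraries (2 and 2). Voom gives deep libraries more weight, so the combined fit leans on RT1 against WT1 and WT2.

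Genes are named by a rule fixed before the data were examined. It takes Tet2, Rhoa and Vav1 whatever their values. It takes the 10 genes with the largest change in each direction among those past the threshold in which every RT library lies beyond every WT library, or, where fewer than 5 pass, the 5 with the smallest p. It leaves out predicted genes and immunoglobulin and T cell receptor segments. In each list past the set test it takes the 3 members with the smallest p, and in each other list up to 2 members past the threshold. The second part was applied again to the recovered reads. A gene and a list that these rules take are not reported here.

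Replicates were compared before use. WT3 and WT4 were the closest of the shallow pairs, with a chi-square statistic per degree of freedom of 1.32 over 2367 genes with 20 or more reads, against 3.30 for RT2 and RT3. This statistic grows with depth, so it does not rank the deep pairs. By Pearson r the pair (0.820) lay close to RT2 and RT3 (0.813) and below the deep pairs (0.845 to 0.945). The difference between WT3 and WT4 exceeded sampling noise (chi-square p = 6.62e-24), which 2 libraries of the same RNA would also do through preparation noise. They were kept as the 2 samples that the labels give, and fits that average or sum them were added. The sex of the mice, read from Xist and Y-linked genes, was male for WT3, WT4 and RT3 and female for the other 4.

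The scripts were tested on simulated data. Counts with 200 changed genes were drawn around the real libraries' means and sizes for RT against WT. Of the genes changed 4-fold, the planned test called 0 of 100, over 9782 genes, although their median estimate was 2.04 for a true log2 change upward of 2. With the library set term it called 13 of 100, and the recovered-read fit called 90 of 100 over 5860 genes. Of the genes changed 2-fold, the 3 fits called 0, 1 and 27 of 100. In the recovered-read fit 4.10% of the calls were false. The counts were drawn for each gene independently, at a negative binomial dispersion of 0.05, with no shift shared by genes of a library. These shares therefore need not carry over to the real libraries, where other groupings gave up to 1012 calls. The totals of all 7 simulated libraries were recovered exactly, and of 5868 simulated genes with 10 or more reads over the shallow libraries 99.1% had every read count recovered.

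Alternatives to the planned test were other pseudocounts, filters, scalings, prior variances, sample weights, a replicate block, a fold threshold and leaving out each library. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. No column of the table was left out.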

Results

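RNA of CD4+ cells sorted from the spleens of C57BL/6 mice was sequenced in 7 libraries, 4 from wild-type mice (WT1 to WT4) and 3 from mice labelled RT (RT1 to RT3). The series describes the second group as lacking Tet2, which encodes a dioxygenase that oxidises 5-methylcytosine in DNA, and carrying G17V RHOA, a form of a small GTPase found in angioimmunoblastic T cell lymphoma. The values were RPKM, reads scaled to gene length and to the library total, for 19589 genes. The libraries fell into 2 sets of very different depth. The totals behind the values, worked out from their steps, were 18566233 reads in WT1, 20033254 in WT2 and 21800352 in RT1. They were 118950 in WT3, 121617 in WT4, 105763 in RT2 and 121659 in RT3. These sets are called deep and shallow below, and each held both genotypes. A single read in a 2-kb gene was worth 0.0269 RPKM in WT1 and 4.73 RPKM in RT2. The number of genes above 0 ran from 11715 to 12985 in the deep libraries and from 7733 to 8561 in the shallow ones. The RPKM values summed to 133044 to 152578 in the deep and 326187 to 366023 in the shallow libraries. A group's mean and SD of RPKM therefore also reflect its mix of the 2 sets. On the log2 scale the first principal component held 36.6% of the variance and separated the deep from the shallow libraries.

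The engineered genes come first. Tet2 (chromosome 3, 133463679 to 133545139, mm10) stood at 6.32, 4.68, 2.86 and 2.79 RPKM in WT1 to WT4. It stood at 5.03, 0.803 and 0 RPKM in RT1 to RT3. The mean was 4.16 ± 1.68 RPKM (SD, n = 4) in WT and 1.95 ± 2.70 RPKM (SD, n = 3) in RT, with a limma adjusted p of 0.662. These levels rest on 1381 and 1105 reads in WT1 and WT2, 1292 in RT1, 4 in each of WT3 and WT4, 1 in RT2 and 0 in RT3. Tet2 in the library labelled RT1 thus lay within the deep wild-type values. A value for the whole gene does not show whether a deleted part is missing, and the deleted part is not given in the sources used here, so Tet2 does not check the labels. Rhoa (chromosome 9, 108306129 to 108337934) had means of 126 ± 64.7 RPKM (SD, n = 4) and 139 ± 71.0 RPKM (SD, n = 3), with a limma adjusted p of 0.968. This spread lay mainly between the library sets. Rhoa stood at 57.8 to 76.3 RPKM in the deep libraries and at 174 to 187 RPKM in the shallow ones. Gene totals do not separate the mutant from the normal Rhoa transcript. Vav1, a guanine nucleotide exchange factor of T cell receptor signalling, had means of 46.2 ± 19.0 and 48.5 ± 13.6 RPKM (limma adjusted p = 0.962).

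The question was which genes differ between RT and wild-type CD4+ splenocytes. In the planned test on log2(RPKM + 1), 4 of 9605 genes were higher in RT and 1 was lower. The 4 genes were Scin, an actin-severing protein, with a log2 fold change of 4.99 ± 0.62 (SE), Vwde at 4.39 ± 0.50, Fam20a at 3.85 ± 0.51 and Myo3b at 3.23 ± 0.42. Their limma adjusted p-values were 0.0473 for Scin and Vwde and 0.0476 for Fam20a and Myo3b. Vwde ran from 0 to 1.13 RPKM in the wild-type libraries and from 16.3 to 36.1 RPKM in the RT libraries. Slc1a4, an amino acid transporter next in rank, did not pass (log2 fold change 3.37, limma adjusted p = 0.0603). The lower gene was the T cell receptor segment Trav6-5, which lies outside the naming rule and was listed at 0 in every RT library and at 8.19 to 22.4 RPKM in wild type. The 5 other genes ranked lowest were Vipr1, Als2cl, Dapl1, Satb1 and Cd55, and none passed the threshold, with limma adjusted p-values from 0.0974 to 0.145. Dapl1, a marker of naive T cells, was listed at 0 in RT and stood at 31.1 ± 21.7 RPKM (SD, n = 4) in wild type. At an unadjusted p under 0.05 there were 435 genes higher and 400 lower. The planned count did not exceed what other groupings of the 7 libraries gave, as 5 of the 35 groupings gave 5 or more calls. The other groupings with as many calls all took their smaller group from 1 library set. Among groupings with the real balance of deep and shallow libraries, the highest other count was 2. Such groupings are too few for a share under 5%. The planned count fell to 0 higher and 0 lower when any of WT2, WT3, RT2 or RT3 was left out, and rose to 10 and 5 without RT1.

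Because 1 read weighed so differently in the 2 sets, the whole reads behind the values were also tested, with a term for the library set. This was chosen after seeing the data. Of 5896 genes tested with limma voom, 562 were higher and 485 lower in RT, 363 and 196 of them by at least 2-fold. Of these, 434 and 422 also had that direction in the deep libraries and in the shallow libraries taken apart. They were called from these same libraries, so this is no separate test, and 56.9% of all tested genes shared a direction in the 2 sets. The 4 genes higher in the planned test were among them. By the naming rule the leading genes were Vwde, Rasgrf1, Scin, Fam20a, Spp1, Muc16, Col16a1, Sostdc1, Reep1 and Gem on the higher side. Spp1, which encodes the secreted protein osteopontin, rose by 5.09 ± 0.33 (log2, SE) and stood at 42.5, 138 and 110 RPKM in RT1 to RT3 against 0.818 to 9.98 RPKM in wild type. Sostdc1, a secreted antagonist of BMP and Wnt signals, rose by 4.30 ± 0.84 (limma voom adjusted p = 0.0117). Siglech, Igfbp4, Vipr1, Adam11, Ifi206, Satb1, Cd7, Ccr7 and Dtx1 were among those on the lower side. Siglech, a member of the dendritic cell list, stood at 94.7 and 46.0 RPM in WT3 and WT4. It stood at 11.3 and 8.77 RPM in WT1 and WT2. Adam11 stood at 56.8 and 36.8 RPM in WT3 and WT4 and at 6.32 and 5.38 RPM in WT1 and WT2. Both genes had 0 reads in every RT library and passed the filter on reads only through WT3 and WT4. Satb1, a chromatin organiser of T cells, fell by 4.17 ± 0.35 on the log2 scale, from 22.9 ± 7.35 to 1.79 ± 2.03 RPKM (SD, n = 4 and 3). Ccr7, the chemokine receptor that brings naive T cells into lymphoid tissue, fell by 3.46 ± 0.33 (limma voom adjusted p = 0.000727). Without RT1, the only deep RT library, the same limma voom fit called 0 higher and 0 lower, with 163 higher and 317 lower at an unadjusted p under 0.05. Every gene given below as risen or fallen was therefore uncalled in that fit, whether or not this is repeated. The median standard error of the 1047 called genes went from 0.20 to 0.83 (log2), while their median absolute log2 fold change went from 1.04 to 0.91. Of these genes 856 kept their direction, the same count as the 434 and 422 above. Without RT1 the genotype effect comes from the shallow libraries alone, so this is no further check. Satb1 was then at -3.94 ± 1.90, Spp1 at 3.62 ± 1.08, Sostdc1 at 2.48 ± 2.20 and Ccr7 at -2.30 ± 1.34. Of 39 named genes called in this fit, 16 moved by over 1.5 times, 8 of them toward 0, such as Rasgrf1 from 7.21 to 3.58, Igfbp4 from -5.34 to -2.60 and Dtx1 from -3.35 to -1.54. Without WT2, Sostdc1 was at 2.78, Rasgrf1 at 4.01 and Muc16 at 3.36 instead of 5.06. The shallow libraries taken alone, which also lack RT1, gave 144 higher and 192 lower. Pdcd1, for example, was at 2.83 in both fits. Its limma voom adjusted p was 0.477 without RT1 and 6.02e-07 in the shallow libraries alone. When only RT1 is left out, WT1 and WT2 still enter the variance estimate but not the genotype effect. The 0 calls without RT1 thus do not show that each call rests on RT1 alone.

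**Figure D1:**
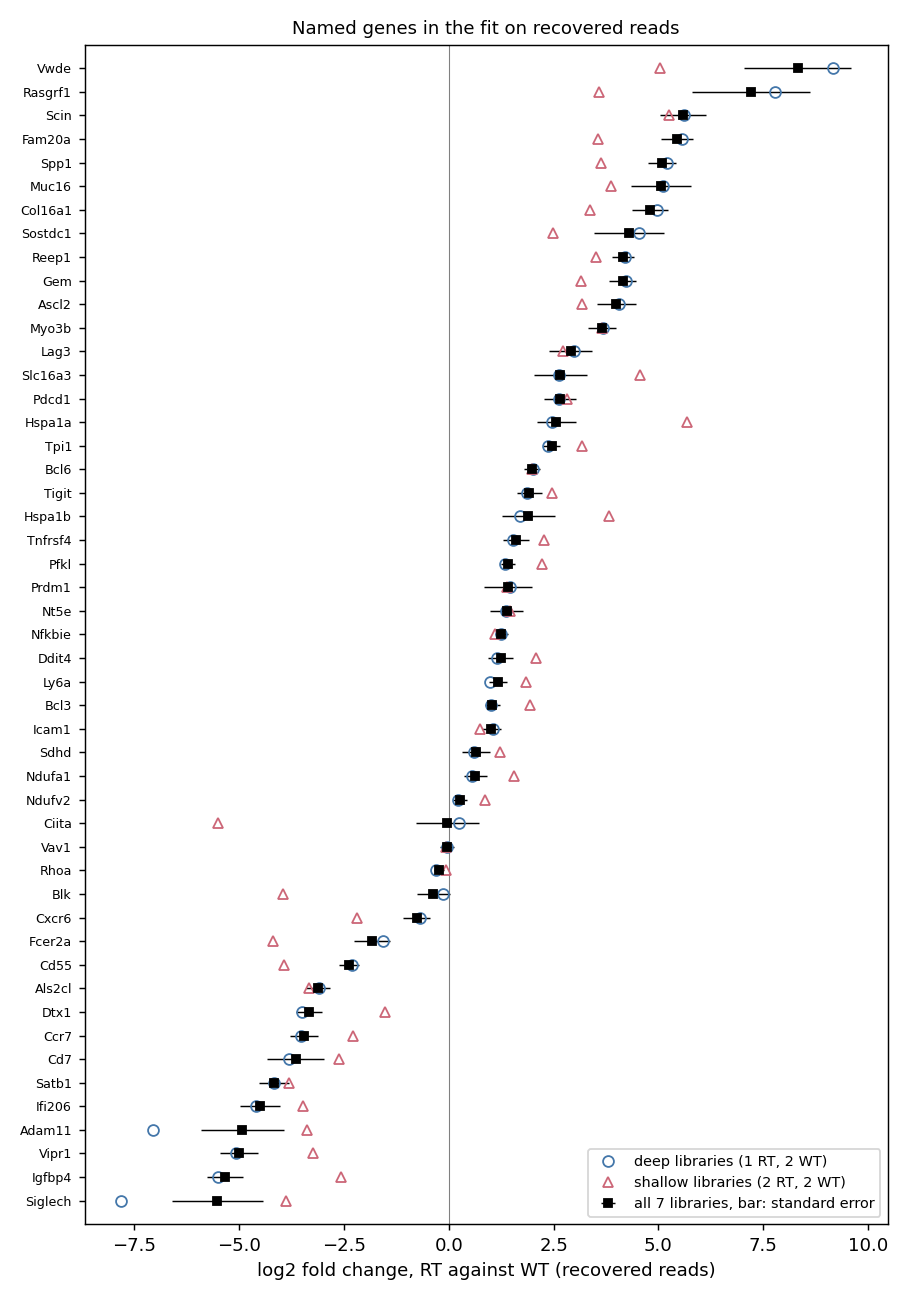
The log2 fold change of RT against WT in 49 named genes from the recovered reads. Black squares with standard errors are all 7 libraries, circles the deep set (1 RT, 2 WT) and triangles the shallow set (2 RT, 2 WT). Many were named because every RT library lies beyond every WT library, so their shared direction in the 2 sets is no test of it. Ciita lies at 0.24 in the deep and -5.51 in the shallow set.

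The 2 sets share no library, so the direction of the genes called in one can be looked up in the other. The deep calls rest on 1 RT library and by themselves do not separate genotype from that mouse. The shallow calls have WT3 and WT4 as their wild type. If these are the same RNA, the shallow calls do not separate genotype from 1 wild-type mouse either. Of 144 genes higher in RT in the shallow libraries alone, 84.7% were also higher in the deep ones, where 47.2% of all tested genes were higher. Of 65 genes lower in the deep libraries alone, 92.3% were lower in the shallow ones, against 53.2% of all genes. The other 2 directions carried over poorly. Of 142 genes higher in the deep libraries alone, 52.8% were higher in the shallow ones, where 46.8% of all genes were. Of 192 genes lower in the shallow libraries alone, 56.8% were lower in the deep ones, against 52.8% of all genes. Across genes, which are not independent replicates, the fold changes of the 2 sets had a Pearson r of 0.150 and a Spearman correlation of 0.195.

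Genes of T follicular helper cells, the CD4+ cells that help B cells in germinal centres, were higher in RT in both library sets. Of every 1000000 recovered reads (RPM), these genes held 1834 to 3059 in the 4 wild-type libraries and 6111 to 7351 in the 3 RT libraries. In the recovered reads 17 of 21 members rose and 0 fell (18 and 0 adjusted over the list alone). The median log2 fold change was 1.52 in the deep and 1.34 in the shallow libraries. Ascl2, a transcription factor that starts the follicular helper programme, rose by 4.00 ± 0.46 (log2, SE), Pdcd1, which encodes the receptor PD-1, by 2.66 ± 0.38, and Bcl6, the lineage regulator, by 1.99 ± 0.19. Bcl6 went from 6.20 ± 1.84 to 26.9 ± 6.53 RPKM (SD, n = 4 and 3). In the planned test 0 members passed over all genes and 13 rose adjusted over the list alone, with a median log2 fold change of 1.58. The list passed camera at an adjusted p of 2.2e-14 with the preset correlation but not with an estimated one, adjusted p = 0.454. The mean level per library was 3.92 ± 0.61 (SD, n = 4) in wild type and 5.59 ± 0.42 (SD, n = 3) in RT, higher in 3 of 3 RT libraries than in any wild-type one. The two-sided exact permutation p was 0.0571, the smallest that 4 against 3 can give, and 0.200 adjusted over 7 lists.

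Genes of naive T cells were lower in RT in both sets. Together they held 6141 to 8476 RPM in wild type and 2399 to 3386 RPM in RT. Of 18 members in the recovered reads 0 rose and 16 fell (17 adjusted over the list alone), with medians of -2.08 in the deep and -2.10 in the shallow libraries. Besides Ccr7 and Satb1, Als2cl fell by 3.12 ± 0.28 on the log2 scale (limma voom adjusted p = 0.000626). In the planned test 0 of 21 members passed over all genes and 15 fell adjusted over the list alone, with a median of -1.86. Camera gave an adjusted p of 1.19e-16, and an adjusted p = 0.454 with an estimated correlation.

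**Figure D2:**
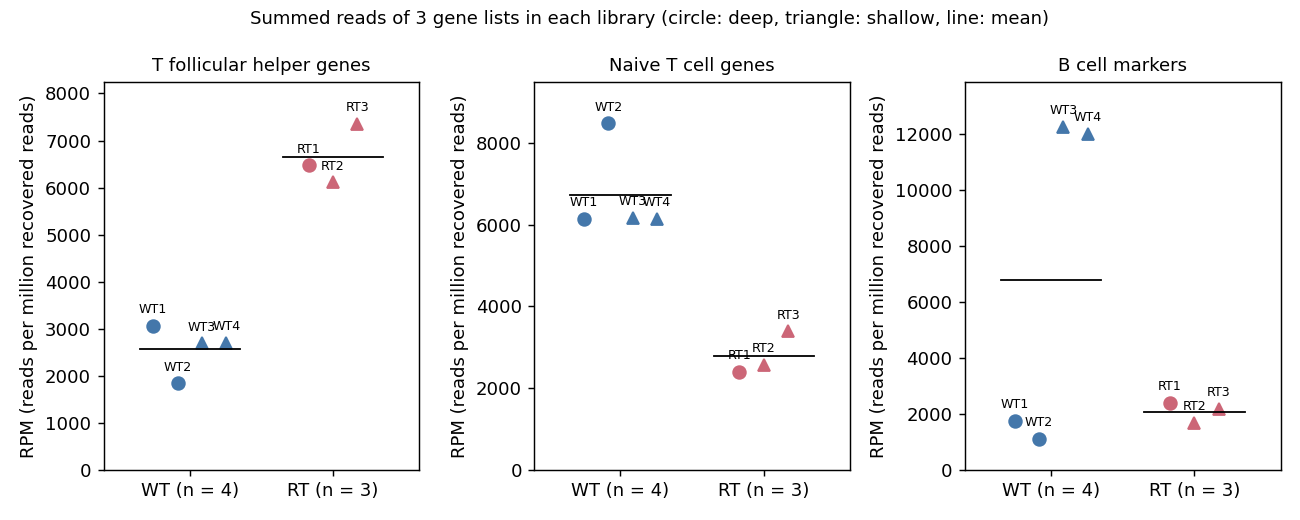
Reads of 3 gene lists, as RPM, in each of the 7 libraries, with the mean of each group as a line, circles for deep and triangles for shallow libraries. The RT libraries lie between 6111 and 7351 for T follicular helper genes and between 2399 and 3386 for naive T cell genes. B cell markers lie at 12258 and 12007 in WT3 and WT4 and stay between 1097 and 2383 in the other 5 libraries.

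Inhibitory receptor and regulatory T cell genes passed the planned set test as higher in RT. Of 9 inhibitory receptor genes in the recovered reads, 7 rose and 0 fell (7 adjusted over the list alone), with a median log2 fold change of 1.50. Lag3, which binds MHC class II, rose by 2.91 ± 0.51 and Tigit by 1.92 ± 0.30. Pdcd1, Btla and Tox stand in this list and in the follicular helper list. Of 13 regulatory T cell genes 6 rose, 1 fell and 6 did neither, and the counts adjusted over the list alone were equal. Tigit, Nt5e, an ectonucleotidase that rose by 1.38 ± 0.39 (0.79 without WT2), and Tnfrsf4, a costimulatory receptor that rose by 1.60 ± 0.30, were among the 6. The member that fell was Il2ra, the high-affinity interleukin 2 receptor chain, chosen after its value was seen. Its log2 fold change was -1.86 over all libraries, -1.93 in the deep ones and 0.09 in the shallow ones. In the planned test 0 members of either list passed over all genes. The medians were 0.45 and 1.16 and the camera adjusted p-values 0.0324 and 0.00152. With an estimated correlation they were adjusted p = 0.562 for inhibitory receptors and adjusted p = 0.464 for regulatory T cell genes.

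The effector and memory list was mixed. It passed camera in the planned test with a median of 0.86 (adjusted p = 0.0289, and adjusted p = 0.617 with an estimated correlation). Of 19 members in the recovered reads 4 rose and 2 fell, and the medians were -0.11 in the deep and 0.84 in the shallow libraries. Ly6a rose by 1.17 ± 0.22 (1.85 ± 0.41 without RT1, uncalled). Prdm1, which encodes a repressor that opposes Bcl6, and the chemokine receptor Cxcr6 did not pass, with log2 fold changes of 1.41 ± 0.58 and -0.77 ± 0.32. Without WT2, Prdm1 was at 0.43, uncalled, and Cxcr6 at -1.15, called (limma voom adjusted p = 0.00543). Without RT1, Cxcr6 was at -2.19 ± 1.42, uncalled.

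The glycolysis list passed the planned set test as higher. Of 17 members in the recovered reads 10 rose, 2 fell and 5 did neither (11 and 2 called adjusted over the list alone), and the medians were 0.69 in the deep and 1.50 in the shallow libraries. Tpi1, triosephosphate isomerase, rose by 2.45 ± 0.21, the lactate exporter gene Slc16a3 by 2.66 ± 0.63 and the phosphofructokinase gene Pfkl by 1.41 ± 0.16. Without RT1 none of these was called, with Tpi1 at 3.18 ± 0.61, Slc16a3 at 4.57 ± 3.44 and Pfkl at 2.22 ± 0.53. Slc16a3 was at 1.46 without WT2. Pdk1 and Slc2a3 fell. In the planned test 0 members passed over all genes and 5 rose and 1 fell adjusted over the list alone. The median was 1.23 and the camera adjusted p 7.83e-07, with an adjusted p = 0.464 at an estimated correlation. Oxidative phosphorylation genes had a planned median of 0.71 (camera adjusted p = 0.00152, and adjusted p = 0.617 with an estimated correlation). In the recovered reads only 1 of 29 members rose and the list did not pass camera (adjusted p = 0.157). Ndufa1 had a log2 fold change of 0.64 ± 0.27, Sdhd of 0.65 ± 0.33 and Ndufv2 of 0.27 ± 0.17, and none of the 3 passed. Without WT2, Ndufa1 at 1.01 and Sdhd at 1.12 were called, and Ndufv2 at 0.36 was not.

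The lists of NF-kB targets and of stress genes also passed the planned set test as higher, the second with few called members. Of 17 NF-kB targets in the recovered reads 9 rose and 0 fell (10 and 1 adjusted over the list alone). Of the 9, 8 had that direction in each set. Nfkbie rose by 1.25 ± 0.15, Bcl3 by 1.04 ± 0.19 (1.93 ± 1.09 without RT1, uncalled) and the adhesion molecule gene Icam1 by 1.01 ± 0.23. The planned median was 0.95 and the camera adjusted p 0.000369, against an adjusted p = 0.562 with an estimated correlation. Of 14 heat shock and stress genes 3 rose, 0 fell and 11 did neither, with a median of 0.26. Ddit4, an inhibitor of mTORC1 signalling, rose by 1.23 ± 0.29 and the heat shock gene Hspa1a by 2.57 ± 0.46, while without RT1 they were uncalled at 2.08 ± 0.93 and 5.65 ± 2.51. Its near-identical neighbour Hspa1b did not pass (1.90 ± 0.62), and the split of reads between the pair is uncertain. Hspa1b was called without WT2, at 2.48 (limma voom adjusted p = 0.0093), and uncalled without RT1, at 3.82 ± 2.09. The planned median of this list was 0.88 with a camera adjusted p of 2.62e-05, and an adjusted p = 0.464 with an estimated correlation.

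The Src and Abl family kinases had a planned median of -0.96 and passed camera (adjusted p = 0.00121, and adjusted p = 0.464 with an estimated correlation). The direction turned in the recovered reads, where 2 of 10 members rose, 0 fell and camera gave an adjusted p of 0.224. The medians were 0.28 in the deep and -1.86 in the shallow libraries. The 3 leading members were Blk, a B cell kinase, at 24.9 and 21.3 RPKM in WT3 and WT4 and 0 to 2.57 RPKM elsewhere, Kit and Ddr1. Kit and Ddr1 were listed at 0 in RT2 and RT3 and held 5 or fewer reads in all shallow libraries together.

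The other lists of T cell genes and of cell processes did not pass the set test in the planned fit. T cell receptor signalling had a median of 0.23 (camera adjusted p = 0.682), and in the recovered reads 3 of 32 members rose and 6 fell (6 and 6 adjusted over the list alone). DNA methylation genes had a median of -0.43 (adjusted p = 0.302), Th1 and cytotoxic genes 1.11 (0.146), Th2 genes 0.34 (0.146) and Th17 genes 0.39 (0.162). In the recovered reads the Th1 and cytotoxic list had the other direction, with a median of -0.70, 1 member rising and 4 falling. The 2 sets differed, with medians of -0.90 in the deep and 1.82 in the shallow libraries (shallow camera adjusted p = 1.72e-07). Immediate early genes stood at 0.25 (0.302), proliferation genes at 0.16 (0.701) and interferon-stimulated genes at 0.31 (0.282). Cytoplasmic ribosomal protein genes stood at -0.03 (0.904). In the recovered reads the ribosomal list passed camera as lower (adjusted p = 0.00026), but not with an estimated correlation (adjusted p = 0.767) or fry (adjusted p = 0.306). Of its 34 members 0 rose and 0 fell, with medians of -0.75 in the deep and 0.03 in the shallow libraries.

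Markers of other spleen cells differed between libraries. B cell markers were lower in RT in the planned test (median -1.72, camera adjusted p = 2.23e-07, and adjusted p = 0.514 with an estimated correlation). The markers held 12258 and 12007 RPM in WT3 and WT4 and 1097 to 2383 RPM in the other libraries. Immunoglobulin genes made up 14.8% and 16.3% of the RPKM total in WT3 and WT4 and at most 3.53% elsewhere. The B cell median was -3.56 in the shallow libraries and 0.62 in the deep ones. Of 20 members in the recovered reads 0 rose, 1 fell and 19 did neither, with a median of -0.040 and a camera adjusted p of 0.859. The 1 was Fcer2a, which encodes CD23 and fell by 1.83 ± 0.42 (log2; -4.20 ± 1.06 without RT1, uncalled), while Ciita, the regulator of MHC class II genes, did not pass. The mean level of the B cell list was 4.46 ± 1.87 (SD, n = 4) in wild type and 2.74 ± 0.59 (SD, n = 3) in RT, with a two-sided exact permutation p of 0.286. CD8 T and natural killer cell markers were lower in the planned test (median -0.75, camera adjusted p = 0.0179, and adjusted p = 0.464 with an estimated correlation). Klrd1, Cd8a and Crtam, its leading members, held 3 or fewer reads in each shallow library. The summed reads did not follow this: the list held 543 to 1069 RPM in RT and 372 to 709 RPM in wild type, and these ranges overlap. Only 2 members could be tested there, with 1 rising, 0 falling and a median of 1.17, or 1.20 in the deep and -0.47 in the shallow libraries. The exact permutation p of this list's mean level was 0.0571 and 0.200 adjusted over 7 lists.

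The remaining lists of other cell types did not pass in the planned test. Plasma cell markers had a median of -0.27 and a mean of -1.31 (camera adjusted p = 0.0527), and dendritic cell markers a median of -1.16 (0.0536). Their medians had the other sign in the recovered reads, 0.72 and 0.30, but for dendritic cells the mean was -0.81, with 1 member rising and 2 falling (camera adjusted p = 0.914). Erythroid and platelet markers stood at -0.84 (0.108). The exact permutation p-values of the 3 lists were 0.343, 0.400 and 0.229. The 2 sets differed here too. Plasma cell medians were 1.17 in the deep and -2.79 in the shallow libraries (shallow camera adjusted p = 6.02e-06), dendritic cell medians 0.49 and -2.62 (0.0314) and erythroid and platelet medians 0.25 and -2.73 (1.01e-05). WT3 and WT4 stood apart in each, as B cell markers did. They held 2473 and 2643 RPM in plasma cell markers against 306 to 801 RPM elsewhere, and 900 and 902 RPM in dendritic cell markers against 223 to 384 RPM. For erythroid and platelet markers the values were 1809 and 1750 RPM against 168 to 453 RPM. Monocyte, macrophage and granulocyte markers had a median of 0.08, a mean of -0.04 (camera adjusted p = 0.682) and an exact permutation p of 1. In the recovered reads this list was higher, as 9 of 12 members rose, with a camera adjusted p of 1.31e-07 and an adjusted p = 0.547 with an estimated correlation. The direction differed between the sets, with medians of 2.29 in the deep and -1.54 in the shallow libraries. RT1 held 7404 RPM in these markers, against 866 to 2681 RPM in the other 6 libraries.

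**Figure D3:**
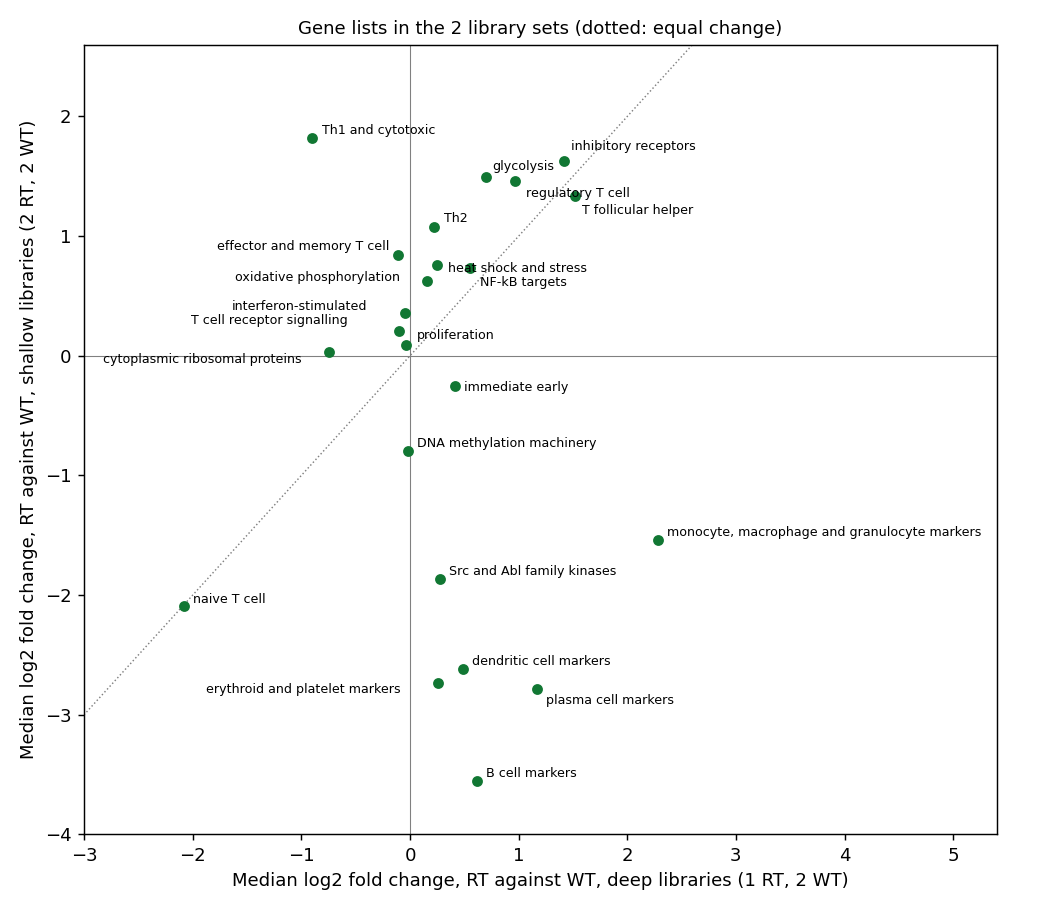
Median log2 fold change of RT against WT over each of 23 gene lists, in the deep libraries (x axis) and the shallow libraries (y axis). The naive T cell list lies at -2.08 and -2.10 and the T follicular helper list at 1.52 and 1.34, near the dotted line of equal change. B cell markers lie at 0.62 and -3.56 and monocyte, macrophage and granulocyte markers at 2.29 and -1.54, far from it.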

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

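The tests in this part were chosen after the results were seen, except those of other groupings of the libraries. Among 65 comparisons of the 4 wild-type libraries, 3 had a library standing far from the others. For 4 independent, normally distributed values chance gives about 1 in 20. The wild-type libraries come from sets of different depth and some values are 0, so the 3 cannot be judged against that rate. Rasgrf1 was at 0.282 RPKM in WT1 and listed at 0 in the other 3, so that the gap filled the whole range (ratio 1). Muc16 was at 0.131 RPKM in WT1 and at most 0.0133 RPKM elsewhere, a gap of 0.899 of the range. Rasgrf1 and Muc16 stood at 6.32 and 6.98 RPM in WT1. The limits at 0 reads were 28.4 RPM in WT3 and 27.6 RPM in WT4, so these libraries were too shallow to show such levels. The level of CD8 T and natural killer cell markers was 3.45 in WT4 and 2.21 to 2.40 in the others, a gap of 0.842 of the range. In summed reads WT4 stood less apart, at 709 RPM against 372 to 616 RPM.

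B cell markers were lower in RT in the planned test. B cell RNA in WT3 and WT4 may account for this: the markers had a median log2 difference of 2.68 between these libraries and WT1 and WT2, although the cells had been sorted for CD4. Among abundant transcripts of such cells, immunoglobulin genes took 14.8% and 16.3% of RPKM in WT3 and WT4. WT1 and WT2 belong to the other library set. RT2 and RT3, shallow like WT3 and WT4, held 1669 and 2183 RPM in these markers, within the 1097 to 2383 RPM of the deep libraries. This argues against the set as the cause, unless genotype lowered the markers in RT2 and RT3. An effect of genotype on these markers cannot be told apart from B cell RNA in WT3 and WT4. The deep libraries, with a median of 0.62, hold only 1 RT library.

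WT3 and WT4 resembled each other more than the other shallow pairs did. The median chi-square over genes was 1.20 times its value under sampling noise, against 2.52 for RT2 and RT3. The same cells or RNA sequenced as 2 libraries could give this, but 2 separate mice that are alike are not excluded. RT2 and RT3 differ in sex, so they are no close reference for such mice. WT3 and WT4 were both male and both carried the B cell markers. No biological explanation was tested.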

How the results depend on the processing

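Alternatives on recovered reads, the library set term and the averaged WT3 and WT4 were chosen after seeing the data, and the cause of each change below was not tested unless given. Against 4 genes higher and 1 lower in the planned test, a pseudocount of 0.1 or 0.5, no filter on low values, a mean of 5 RPKM or more and the replicate block each gave 0 and 0. Scaling every library to the same sum gave 7 and 5, quantile normalization 20 and 7, trimmed mean scaling 10 and 6, equal medians 4 and 2 and sample weights 18 higher. The library set term gave 21 and 5, and averaging WT3 and WT4 gave 2 and 0 with fewer samples. A constant or robust prior and a 2-fold limit stayed within 1.5 times.

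Recovered reads gave 562 higher and 485 lower with the library set term and 301 and 203 without it. Trimmed mean scaling gave 523 and 414, WT3 and WT4 summed 386 and 323, shallow libraries alone 144 and 192, deep libraries alone 142 and 65, and a further term for sex 527 and 461. Of the calls with WT3 and WT4 summed, 706 were shared with the fit that kept them apart. Leaving out each library in turn gave 0 to 10 higher and 0 to 5 lower in the planned test. In the recovered reads it gave 0 to 760 higher and 0 to 645 lower, with the 0 in each direction coming from leaving out RT1.

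Replicate numbers occur in both groups, and whether they pair the libraries could not be told. The deviations of RT1 and WT1 had a correlation of 0.43, those of RT2 and WT2 of -0.18 and those of RT3 and WT3 of 0.18. Correlations were positive within a library set and negative between the sets, and RT2 and WT2 lie in different sets. Within its set RT1 correlated more with WT1 than with WT2 (0.34), and RT3 about equally with WT3 and WT4 (0.18). The replicate block on 6 libraries gave 0 calls in either direction and 11 lists.

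The planned test called 12 gene lists, and 0 with an estimated correlation, with fry, or with an estimated correlation on recovered reads. Under the other planned settings 11 to 15 lists passed. The follicular helper and naive lists passed in all 19 of these settings, with adjusted p-values up to 1.72e-08 and 3e-08. The effector and memory list passed in 12 of 19 and the CD8 T and natural killer list in 11 of 18. The inhibitory receptor and oxidative phosphorylation lists passed in 18 of 19 each, with adjusted p-values up to 0.0825 and 0.132. On recovered reads 9 lists passed camera with the preset correlation. With fry there, the naive list passed (adjusted p = 0.0127) and the follicular helper list did not (0.0524).

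Among named genes, list levels and lists past the planned set test with a set test on recovered reads, directions turned for 6. Beyond these, on recovered reads 5 lists not past the planned set test had medians of another sign: Th1 and cytotoxic -0.70, T cell receptor signalling -0.027, proliferation -0.063, plasma cell 0.72 and dendritic cell 0.30. So did the CD8 T and natural killer list, at 1.17 over 2 genes. The Src and Abl list, lower in the planned test, was toward higher on recovered reads with the set term (adjusted p = 0.224), without it (0.16), with trimmed scaling (0.233), with WT3 and WT4 summed (0.156), in the deep libraries alone (0.0615), with sex (0.173) and with an estimated correlation (0.767). B cell markers were toward higher under the same settings, at 0.859, 0.699, 0.977, 0.518, 0.00555, 0.363 and 0.984, past the threshold only in the deep libraries. In the shallow libraries alone both lists stayed lower (adjusted p = 0.0075 and 1.08e-19). Leaving out libraries in the planned test, both stayed lower, at 0.000177 to 0.0147 and 1.17e-13 to 0.000147. On recovered reads the ranges were 0.0019 to 0.297 and 1.33e-17 to 0.694. The lowest of each came without RT1, where the list was lower, and B cell markers were also toward lower without WT2 (0.663). The Src and Abl list passed as higher without WT3 (camera adjusted p = 0.0498).

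Rhoa, uncalled at 0.13, was -0.091 with equal sums, -0.30 with quantiles and -0.12 with the set term, and -0.17 to 0.67 leaving out libraries. On recovered reads it was -0.24 with the set term, -0.082 without, -0.20 trimmed, -0.23 summed, -0.063 shallow, -0.30 deep and -0.27 with sex, and -0.27 to -0.063 leaving out libraries. Vav1, uncalled at 0.11, was -0.11, -0.19 and -0.016 under the first 3 of these settings, and -0.085 to 0.36 leaving out libraries. On recovered reads it was -0.042, -0.049, -0.024, -0.046, -0.069, -0.035 and -0.047 in the same order, and -0.16 to 0.093 leaving out libraries. Ciita, at -2.55, was -3.39 to -2.13 leaving out libraries. On recovered reads it was 0.045 with WT3 and WT4 summed, 0.24 in the deep libraries and 0.12 with sex, and -5.51 to 0.68 leaving out libraries. The level of monocyte, macrophage and granulocyte markers, at -0.043, ran from -0.86 to 0.51 leaving out libraries.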

Other observations

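The tests of sex, of B cell RNA and of receptor segments in this part were chosen after the results were seen, and those of other groupings of the libraries were not. The leading T cell receptor beta segment took a larger share in RT. The leading Trbv segment took 12.4%, 13.9%, 12.5% and 11.8% of Trbv reads in WT1 to WT4, of 2430, 2733, 48 and 51 reads. The Wilson 95% intervals of WT3 (5.86% to 24.7%) and WT4 (5.51% to 23.4%) are wide and hold the share of RT1. It took 18.7% of 3184 reads in RT1 (Trbv13-2, Wilson 95% interval 17.4% to 20.1%), 32.8% of 67 in RT2 (Trbv13-2, 22.8% to 44.7%) and 50.0% of 90 in RT3 (Trbv3, 39.9% to 60.1%). In RT2 the related segment Trbv13-1 took a further 25.4%, and reads of close paralogs may be split between them. The effective number of segments was 4.77 in RT2 and 3.53 in RT3, but 12.4 in RT1, within the 12.1 to 13.8 of wild type. Of Trav reads, Trav7-2 took 13.5% in RT1, where the leading segments of WT1 and WT2 took 4.20% and 4.97%. The leading Trav share was 14.3% in WT3 and 17.9% in WT4, both above RT1, and 20.8% in RT2 and 18.4% in RT3, and the exact permutation p for Trav was 0.229. The shallow libraries held 24 to 38 Trav reads each. A few expanded T cell clones in RT are a candidate explanation, with a different leading segment in RT3 than in RT1 and RT2. The Trbv share was higher in 3 of 3 RT libraries than in any wild-type one, with a two-sided exact permutation p of 0.0571, the smallest this design can give. Segment use alone does not identify clones, so this stays a hypothesis.

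The higher follicular helper and lower naive genes in RT were weighed against 2 other explanations. If B cell RNA in WT3 and WT4 were the cause, the shift would be weak in the deep libraries, which hold neither, but the follicular helper median there was 1.13 times that in the shallow ones. With a term for sex the median stayed at 1.51, against 1.50 without it. That term rests on RT2, the only female among the shallow libraries, so it decides little. The deep libraries were all female and had a median of 1.52, so sex cannot be the cause there, though they hold 1 RT library. The set tests leave chance open: they passed with the preset correlation of genes and not with an estimated one, under which 0 lists passed. Fry on the recovered reads gave an adjusted p of 0.0127 for the naive and 0.0524 for the follicular helper list. That fit was chosen after seeing the data and leans on RT1. Fry in the planned test gave 0.0921 and 0.109. Whether genotype shifts sorted CD4+ cells from naive to follicular helper cells stays open as a hypothesis. It was not tested, and bulk RNA does not separate a change in cell numbers from one in expression per cell.

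Other groupings of the 7 libraries bear on the counts of genes. In the planned test 5 of 35 groupings gave at least the 5 calls of the real one, and the highest other gave 1571, so chance cannot be excluded. That highest one set the 3 deep libraries against the 4 shallow ones, a structure of the libraries that is distinct from genotype. It is not balanced over genotype, and the planned test has no term for it. The others, with 20, 9 and 7 calls, took their smaller group from the shallow libraries alone. Among the 18 groupings that keep the balance of the sets, the highest other gave 2, but 18 are too few for a share under 5%. In the recovered-read fit 1 of 34 groupings, the real one, gave 1047 calls, and the highest other gave 1012. The fit has a term for the library set, though, and only 18 groupings keep the balance of the sets, too few for a share under 5%. Among these the highest other gave 814. In all, 9 other groupings gave 358 to 1012 calls, and all 9 set RT1 against both WT1 and WT2. Counting only calls with the same direction in both sets, 1 of 30 groupings, the real one, gave 856, and the highest other gave 683, or 506 among the 18.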
